A study of Gallus gallus with 12 samples.

How the data were processed

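The series measured gene expression in the gut wall of chick (Gallus gallus) embryos at embryonic day 14 with Light-seq, a spatial RNA-sequencing method. In Light-seq, RNA is reverse transcribed on the tissue section, regions outlined by hand under the microscope receive DNA barcodes by light-directed crosslinking, and the barcoded cDNA is taken off the slide and sequenced. Per the series text, 3 regions of the mesoderm were barcoded in each sample: the subepithelial mesenchyme, the inner longitudinal muscle and the inner face of the circumferential muscle. The samples came from midgut or hindgut of embryos incubated at 38 °C. Per the labels, RCAS retrovirus had been electroporated at Hamburger-Hamilton stage 17 into the mesoderm at midgut level that forms the gut wall, carrying mGFP, a fluorescent protein, as a control or Hoxd13. The 12 samples formed 3 groups of 4: midgut with mGFP, midgut with Hoxd13 and hindgut with mGFP, called midgut, Hoxd13 midgut and hindgut here. Each sample gave 1 sequencing library with reads of all 3 layers, so the table held 36 columns of counts.

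The authors deposited whole-number counts per gene, sample and layer, with a different total in each column, so no normalisation was visible in them. Reads were assigned to a layer by its barcode, per the series text. The genome build was GRCg6a, and UMI-tools, STAR, MultiQC, featureCounts and DESeq2 were listed without roles, versions or settings, per the submitters' processing notes. Whether the deposited counts are of reads or of unique molecules is not given in the sources used here. The intervals and floors below therefore cover counting error only. The table held 17138 genes, none of them at 0 in all 36 columns, so the file lists no gene without a count. Of these, 11801 had a gene symbol and 5337 only an Ensembl identifier. The reference table used here, for assembly GRCg7b, gives no Ensembl identifiers, so 0 of the latter were matched; 11305 of the symbols were matched, and the table served only for chromosome membership (528 Z-linked and 4 W-linked genes). Among the symbols, 7 entries read as calendar dates (for example 5-Sep), as spreadsheet programs make of some gene symbols, and were left as they stood. Genes that share reads with close copies, such as W-linked genes with their Z-linked partners, ribosomal protein genes with their pseudogenes and globin genes with each other, are uncertain, because the counting rule for such reads is not given in the sources used here.

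Total counts ranged from 210803 to 903222 per sample in the mesenchyme (median 356599), from 11233 to 49535 in the longitudinal muscle (median 19703.5) and from 19920 to 112252 in the circumferential muscle (median 40113.5). A floor of 3 counts, the upper limit that a count of 0 allows at 95% confidence, was 3.32 to 14.2 CPM (counts scaled to the usual common total) in a mesenchyme sample. It was 60.6 to 267 CPM in the longitudinal muscle and 26.7 to 151 CPM in the circumferential muscle. Folds against a group at 0 were computed against 3 counts over the whole group, and ratios against 1 to 3 counts are given with exact intervals. Such folds leave out the counting error of the other group, so they are not lower confidence limits. No pair of replicates of a group agreed within sampling noise in a chi-square test of their counts over genes, so all were kept as separate samples. Counts of reads would exceed sampling noise as well, and the test does not show that the samples are separate embryos.

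Tests were run in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test, TMM factors, low-count filter of edgeR with a minimum count of 10 and a minimum total of 15) on the counts as deposited, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. In each layer the 12 samples shared 1 estimate of the spread, and hindgut was compared with midgut and Hoxd13 midgut with midgut. In the mesenchyme, the layer the design text names for its own tests, hindgut was also compared with Hoxd13 midgut. The layers were compared in a fit of all 36 columns with the sample as a block, averaged over the groups. The same fit tested whether the effect of hindgut or of Hoxd13 in the mesenchyme differed from its mean in both muscle layers. CPM of single genes use TMM library sizes, except for HOXD13 and for sums over genes, which use the total counts. A sample is said to lie in the direction of a change when it lies beyond all samples of the other group, or, between layers, when its muscle region lies beyond its own mesenchyme. Standard errors are the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. Genes changed in both comparisons with midgut were set against the count from independent lists, against 50 simulations of unchanged groups that share the midgut samples, and against all 6 assignments of the midgut samples to both comparisons, a pair each. The groups, tests, filters, gene lists, rule for named genes and most alternatives were fixed before the data were examined.

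The 27 gene lists, fixed from general knowledge, were posterior HOX, anterior and middle HOX, TGF-beta signalling, BMP signalling, fibrillar and associated collagens, basement membrane, matrix glycoproteins and proteoglycans, matrix crosslinking and turnover, Hedgehog response, WNT signalling, mechanical response and actomyosin, smooth muscle, fibroblast and mesenchyme, intestinal epithelium, enteric neurons and glia, endothelium, immune cells, erythroid, interstitial cells of Cajal, mesothelium, proliferation, interferon response, immediate early and heat shock, mitochondrially encoded, retinoic acid, FGF signalling and NOTCH signalling. They were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with at least 4 members tested, and adjusted over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Named genes were taken by rule: HOXD13 and the other HOX genes past the filter, the 10 genes with a symbol of smallest p in each direction past the threshold in each mesenchyme comparison, up to 4 members per list of smallest p. To these came up to 10 shared genes per direction, the 6 of smallest p per direction between layers and within muscle layers, and up to 5 per direction for the difference between layers. Where fewer than 5 genes passed, all were named, with the 6 of smallest p as values. HOX genes under the filter are given as counts, chosen by their membership of the HOX lists.

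Alternatives were DESeq2 size factors and TMMwsp factors in edgeR, no low-count filter, a filter with a minimum count of 20, the DESeq2 1.42.0 Wald test, and limma voom with sample quality weights. Further ones were the replicate number as a block (for the fit of all columns, no block), only the compared groups in the fit, a threshold of 0.1, and leaving out each sample in turn. Leaving out Z- and W-linked genes, mitochondrial genes, or the former together with hindgut replicate 1, and testing the lists without that sample, were chosen after seeing the data.

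The code was tested on simulated counts drawn from the real means, library sizes and dispersions, with known changes in 200 of the more highly expressed genes. For hindgut against midgut in the mesenchyme (3859 genes tested) it recovered 21.3% of genes changed 1.5-fold, 68.2% at 2-fold, 100% at 3-fold and 97.7% at 4-fold, and called 3 of 3677 unchanged genes. Without hindgut replicate 1 (4037 genes) recovery was 25.5%, 61.7%, 89.8% and 97.8%, with 6 of 3849 unchanged genes called. In the longitudinal muscle (137 genes) it was 27.3%, 47.6%, 100% and 100%, with 2 of 65 unchanged genes called, and in the circumferential muscle (400 genes) 30.3%, 66.7%, 97.1% and 100%, with 0 of 256. Changed genes made up a large share of those tested in the muscle layers, which eases the adjustment, so recovery there may be overstated. No sample was simulated to stand apart. For circumferential muscle against mesenchyme (717 genes) it was 74.4% at 1.5-fold and 100% at each larger fold, with 4 of 541 unchanged genes called. For the difference between layers (706 genes) it was 14.3%, 63.6%, 91.1% and 97.8%, with 0 of 529.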

Results

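Counts per gene were obtained by Light-seq for 3 layers of the embryonic gut wall in 12 samples, 4 each from control midgut, control hindgut and midgut that misexpressed Hoxd13. The mesenchyme lies directly under the epithelium, with the inner longitudinal muscle and the inner face of the circumferential muscle outside it. Per sample, the mesenchyme held 210803 to 903222 counts, the longitudinal muscle 11233 to 49535 and the circumferential muscle 19920 to 112252. In the mesenchyme, hindgut replicates 1 to 4 had 903222, 210803, 261543 and 454072 counts, Hoxd13 midgut replicates 368053, 369840, 326362 and 407737, and midgut replicates 427619, 307245, 303637 and 345145. The labels do not say whether the 4 replicates of a group are separate embryos, and the regions were drawn by hand, so the p-values below measure only the spread between these samples.

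HOXD13, the transcription factor that was misexpressed, was absent from the control midgut mesenchyme (0 counts in each of 4 samples) and abundant in every Hoxd13 midgut sample (213, 202, 155 and 238 counts). The sum of 808 counts was 253-fold above the midgut floor of 3 counts over the group. The hindgut had 4, 2, 1 and 8 counts (15 in all, at least 3.78-fold above midgut), so the misexpressing midgut exceeded it 67.0-fold. In CPM of the total counts, HOXD13 reached 546 ± 50.1 (SD, n = 4) in the Hoxd13 midgut and 8.84 ± 6.38 in the hindgut. The Hoxd13 midgut was also highest in the longitudinal muscle, with 0, 92 and 2 counts in midgut, Hoxd13 midgut and hindgut, and in the circumferential muscle, with 0, 141 and 5 counts. The hindgut counts there came from 1 and 2 samples and were too few to place hindgut above midgut.

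Some other posterior HOX genes, which mark the hind end of the body axis, separated hindgut from both midgut groups. Summed over 4 hindgut samples, HOXA13 had 82 counts against 0 in midgut, 20.7-fold above the midgut floor. HOXB13 had 79 (19.9-fold), HOXA11 66 (16.6-fold) and HOXA10 36 (9.07-fold), also against 0 in midgut. HOXA13 had 4 counts in the Hoxd13 midgut. HOXD12 had 9 counts in hindgut against 0 in both midgut groups (2.27-fold above the midgut floor). Its 95% counting interval of 2.25 to 9.34 CPM barely cleared that floor of 2.17 CPM. HOXA9 had 20 against 2 in midgut (a ratio of 7.56, 95% counting interval 1.84 to 66.7) and 3 in the Hoxd13 midgut. HOXD11 had 4 counts in hindgut against 0 in both midgut groups, too few to place hindgut above midgut. Others did not separate them: in midgut, Hoxd13 midgut and hindgut HOXC9 had 4, 7 and 3 counts, HOXB9 3, 0 and 2, and HOXC13 1 in each. Of the HOX genes of the anterior and middle part of the clusters, 8 passed the low-count filter, and none of them passed the threshold in hindgut against midgut by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Their fitted log2 changes ran from -1.06 for HOXA4 (adjusted p = 0.22, below all midgut samples in 3 of 4) to 0.10 for HOXC8 (adjusted p = 0.93, below in 0 of 4). Without hindgut replicate 1, HOXA4 was at -2.50 (adjusted p = 0.00024), HOXC6 at -2.31 (adjusted p = 0.00063), HOXB3 at -1.68 (adjusted p = 0.00038) and HOXA3 at -1.50 (adjusted p = 0.00085), all past the threshold. HOXA3 itself had 56 counts in hindgut replicate 1 and 5, 1 and 12 in the other hindgut samples.

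**Figure D1:**
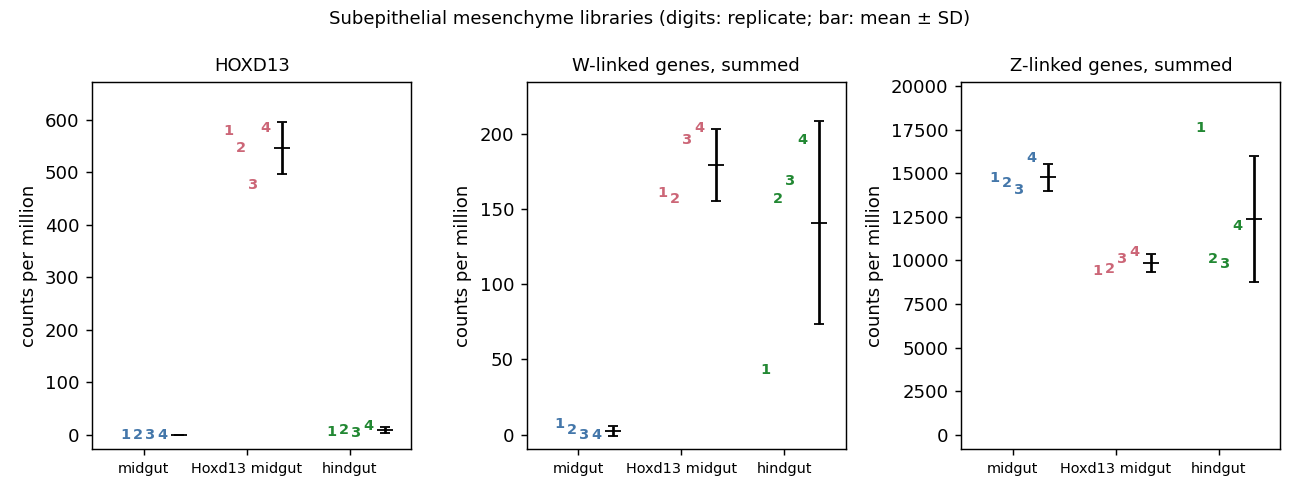
HOXD13, the sum of W-linked genes and the sum of Z-linked genes in CPM for each mesenchyme sample of the 3 groups; digits give the replicate and bars the mean ± SD. Hoxd13 midgut samples average 546 CPM of HOXD13, and W-linked genes lie between 0 and 7.0 CPM in midgut and between 157 and 204 CPM in the Hoxd13 midgut.

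Genes of the W chromosome, which only female chicks carry, were nearly absent from the control midgut and present in every Hoxd13 midgut and hindgut sample. HINTW had 85.5 times the midgut level in the Hoxd13 midgut (95% counting interval 15.0 to 3415) and 61.3 times in hindgut (10.7 to 2449). HNRNPKL had 94.9 times (16.7 to 3787) and 51.4 times (8.92 to 2061), and SPIN1W 26.3 times (6.95 to 223) and 17.0 times (4.44 to 145). W-linked genes summed to 0 to 7.0 CPM in midgut, 157 to 204 CPM in the Hoxd13 midgut and 43.2, 157, 168 and 196 CPM in hindgut replicates 1 to 4. Z-linked genes, which males carry in a double dose, moved the other way: their median log2 change was below that of other chromosomes by -0.40 in the Hoxd13 midgut (95% interval -0.52 to -0.31, 130 Z-linked genes) and by -0.22 in hindgut (-0.37 to -0.12). Without hindgut replicate 1 the difference in hindgut was -0.35 (-0.49 to -0.21, 128 Z-linked genes). Hindgut replicate 1 had a sum of Z-linked genes of 17570 CPM (midgut 14033 to 15840), whereas hindgut replicates 2 to 4 had 10071, 9784 and 11996 CPM. The totals behind these values include mitochondrial counts, with a share of 27.5% in hindgut replicate 1 and 35.9% to 39.0% in midgut. The sum alone does not place that sample above midgut. Both comparisons with midgut therefore held a difference in sex-linked genes beside the difference in tissue or transgene. Chromosomes were taken from the GRCg7b assembly.

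Hindgut was compared with midgut to describe how the mesenchyme of the large intestine differs from that of the small intestine. Several genes of contractile smooth muscle and of the matrix around cells rose in hindgut mesenchyme. PTN, a secreted growth factor, rose by 2.66 ± 0.35 (log2, SE; adjusted p = 0.00044), from 86.3 ± 21.0 to 560 ± 272 CPM (SD, n = 4), and lay above all midgut samples in 4 of 4. TAGLN, an actin-binding protein of smooth muscle, rose by 1.51 ± 0.23 (adjusted p = 0.0014), from 391 ± 73.4 to 1136 ± 454 CPM, above all midgut samples in 3 of 4. Further contractile genes that rose were ACTA1 (1.62), CSRP1 (1.52), DES (1.18), ACTN1 (1.08), MYL9 (1.02) and FLNA (0.91). Matrix genes that rose were the glycoproteins THBS2 (2.13 ± 0.37, adjusted p = 0.0035, 4 of 4 samples) and FBLN1 (1.65 ± 0.27, adjusted p = 0.0025, 4 of 4). SMOC1 (2.95), the proteoglycans VCAN (1.72, Z-linked) and PRELP (0.64), and the collagens COL12A1 and COL4A1 (0.82 each) rose as well. LTBP1, which stores TGF-beta in the matrix, rose by 0.76, and NBL1, a BMP antagonist, by 1.03. The globin genes HBA1 (1.37 ± 0.20, adjusted p = 0.0013, 4 of 4) and HBAD (1.11) rose as well. Erythroid genes summed to 650 ± 170 CPM in hindgut against 273 ± 82.7 CPM in midgut. HBA1 (441 and 166 CPM) and HBAD (178 and 75.1 CPM) made up most of that sum, so it is no separate evidence.

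In hindgut 7 genes fell, and 401 were lower in the fit without hindgut replicate 1. ANPEP, a brush-border peptidase of the epithelium, fell by 0.97 ± 0.25 on the log2 scale (adjusted p = 0.048), from 906 ± 140 to 438 ± 278 CPM, below all midgut samples in 3 of 4. MYH9, the heavy chain of non-muscle myosin, fell by 0.68 (adjusted p = 0.033), COTL1, an actin-binding protein, by 0.82 (adjusted p = 0.048) and RPS3A by 0.50 (adjusted p = 0.048, 4 of 4 samples). RPL17 and NREP, which lie on the Z chromosome, fell by 0.89 and 0.79 (4 of 4 samples each). The growth factor receptor FGFR1 (0.80, adjusted p = 0.057), the NOTCH target HES1 (1.11, adjusted p = 0.061), and the transcription factor TBX3 (-0.78, adjusted p = 0.061) did not pass. Nor did the collagen COL5A1 (0.61, adjusted p = 0.053) or the retinoic acid enzyme ALDH1A3 (-1.10, adjusted p = 0.075). All 5 passed without hindgut replicate 1, with ALDH1A3 at -2.14 (adjusted p = 1.6e-09).

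By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 62 of 4176 genes passed in hindgut against midgut, 55 higher and 7 lower, and 582 had an unadjusted p under 0.05. Hindgut replicate 1 stood apart: without it 825 of 4214 genes passed (424 higher, 401 lower), all 62 among them. Without midgut replicates 1 to 4 in turn the count was 31, 24, 23 and 19, and without hindgut replicates 2, 3 and 4 it was 17, 14 and 27. With only midgut and hindgut in the fit 2 genes passed. Of 28 named calls, 11 passed whichever sample was left out: PTN, HBA1, TAGLN, HNRNPKL, HINTW, FBLN1, THBS2, ACTA1, CSRP1, DES and MYL9. ANPEP, RPS3A and COTL1 passed in only 1 of these 12 fits, the one without hindgut replicate 1, where ANPEP was at -1.63 (adjusted p = 2.9e-13).

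Among gene lists fixed in advance, smooth muscle genes gave the clearest shift in hindgut mesenchyme: 7 of 23 tested rose, 16 when adjusted over the list alone, with a median log2 change of 0.67 (camera, adjusted p = 6.1e-17; adjusted p = 0.2 with an estimated correlation). None of the 9 lists given here passed with a correlation between genes that was estimated. Fibrillar and associated collagens (median 0.40, adjusted p = 0.00085; 1 of 11 higher, 5 adjusted over the list alone; adjusted p = 0.26 with an estimated correlation) and matrix glycoproteins and proteoglycans (0.32, adjusted p = 0.00024; 4 of 22 higher, 8 higher and 1 lower adjusted over the list alone; adjusted p = 0.2 with an estimated correlation) were also shifted up. Endothelium (0.45, adjusted p = 0.0031), mechanical response and actomyosin (0.22, adjusted p = 0.038), TGF-beta signalling (0.16, adjusted p = 0.038) and WNT signalling (0.18, adjusted p = 0.047) passed too. All 4 had adjusted p = 0.2 with an estimated correlation, and adjusted over the list alone 2, 3, 3 and 1 of their genes were higher. Epithelial genes were shifted down (median -0.65, adjusted p = 3.6e-11), with 1 of 22 lower and 11 lower adjusted over the list alone (adjusted p = 0.2 with an estimated correlation). Epithelial genes summed to 5277 ± 821 CPM in midgut and 3169 ± 2091 CPM in hindgut, where replicate 1 had 6287 CPM and the others 1820 to 2328 CPM. Anterior and middle HOX genes were shifted down (-0.85, adjusted p = 0.00015; 3 of 8 lower adjusted over the list alone; adjusted p = 0.2 with an estimated correlation).

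The other lists did not pass in hindgut against midgut: fibroblast and mesenchyme (adjusted p = 0.064), basement membrane (0.064), NOTCH signalling (0.07), Hedgehog response, BMP signalling and mitochondrially encoded genes (0.1 each), and matrix crosslinking and turnover (0.11). Nor did FGF signalling (0.16), immediate early and heat shock genes (0.25), retinoic acid (0.29), mesothelium (0.57), enteric neurons and glia (0.68), proliferation (0.69) or interstitial cells of Cajal (0.7). For mesothelium the median (0.01) and the mean (-0.11) differed in sign. Too few members of 4 lists were expressed for a test in any mesenchyme comparison: posterior HOX (1 gene), immune cells (2), interferon response (2) and erythroid (3, of which HBA1 and HBAD were higher in hindgut).

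Hoxd13 midgut was compared with midgut to find the genes that respond to Hoxd13 in the small intestine. GJA5, a gap junction channel, rose by 3.07 ± 0.36 (log2, SE; adjusted p = 1.4e-05), from 12.7 ± 5.17 to 111 ± 36.7 CPM (SD, n = 4), above all midgut samples in 4 of 4. The sulfotransferase SULT1C3 rose by 2.01 ± 0.28 (adjusted p = 0.00017) and the matrix signalling protein NOV by 1.11 ± 0.19 (adjusted p = 0.0014), each in 4 of 4 samples. The transcription factor ETV6 rose by 1.19 ± 0.23 (adjusted p = 0.0055), the transferrin receptor TFRC by 2.34 ± 0.45 (adjusted p = 0.0056) and the histone gene HIST1H110 by 0.95 ± 0.19 (adjusted p = 0.0066), each in 4 of 4 samples. TAGLN rose by 0.98 ± 0.23 (adjusted p = 0.026), from 391 to 773 ± 37.3 CPM, with MYL9 (0.79), TPM1 (0.60) and the contractility switch RHOA (0.60), and TAGLN and MYL9 lay above all midgut samples in 4 of 4. The mitotic genes BUB1 (1.54) and TOP2A (0.51), the mechanically induced CYR61 (1.47), the transcription factors JUND (0.98) and KLF6 (0.70) and mitochondrial ND4L (0.49) rose too.

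MYL12B, a regulatory light chain of non-muscle myosin, fell most clearly, by 1.90 ± 0.24 on the log2 scale (adjusted p = 3.6e-05), from 111 ± 23.8 to 29.0 ± 3.8 CPM, below all midgut samples in 4 of 4. The guidance molecule SLIT3 fell by 0.95 ± 0.16 (adjusted p = 0.0012) and the adhesion protein SVEP1 by 1.16 ± 0.21 (adjusted p = 0.003), each in 4 of 4 samples. The steroid reductase AKR1D1 fell by 1.88 ± 0.36 (adjusted p = 0.0048), PODXL by 1.06 ± 0.22 (adjusted p = 0.0086) and ISLR2 by 0.84 ± 0.17 (adjusted p = 0.0071), each in 4 of 4 samples. The matrix genes ELN (-0.89), EFEMP1 (-0.93), LAMA5 (-0.58), POSTN (-0.77) and LOX (-0.76, Z-linked) fell, as did the pericyte receptor PDGFRB (-0.95). The transcription factor TBX3 (-0.96), the Hedgehog co-receptor CDON (-0.72), the growth inhibitor BTG2 (-0.84) and ALDH1A3 (-1.20) fell too. The Z-linked RPL17, NREP and RPS6 fell by 1.51, 1.34 and 1.01 (4 of 4 samples each). HOXB7 (-1.76, adjusted p = 0.064), CDX1 (adjusted p = 0.061, lower in 4 of 4 samples), DCN (-0.57, adjusted p = 0.051) and THBS2 (1.32, adjusted p = 0.077) did not pass.

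By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 111 genes passed for Hoxd13, 55 higher and 56 lower, and 702 had an unadjusted p under 0.05. Leaving out midgut replicates 1 to 4 gave 46, 66, 64 and 41 genes, leaving out Hoxd13 midgut replicates 1 to 4 gave 45, 39, 46 and 37, and leaving out hindgut replicate 1, which is in neither group compared, gave 317 of 4214 genes tested. With only midgut and Hoxd13 midgut in the fit 365 genes passed, 106 of the 111 among them. Of 40 named calls, 17 passed whichever sample was left out: HOXD13, GJA5, HNRNPKL, HINTW, SULT1C3, NOV, SPIN1W, ETV6, TFRC, HIST1H110, MYL12B, RPL17, NREP, SLIT3, SVEP1, AKR1D1 and RPS6. TAGLN did not pass without midgut replicate 2 (adjusted p = 0.1), and MYL9 did not without Hoxd13 midgut replicate 3 (adjusted p = 0.12).

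Mitochondrially encoded genes were shifted up in the Hoxd13 midgut (median 0.34, camera adjusted p = 0.002; 1 of 13 higher, 1 adjusted over the list alone; adjusted p = 0.75 with an estimated correlation). The mitochondrial share of all counts was 41.9 ± 1.02% against 37.8 ± 1.35% in midgut and 32.4 ± 3.47% in hindgut (SD, n = 4). Proliferation genes (0.32, adjusted p = 0.0022; 2 of 27 higher, 3 adjusted over the list alone) and smooth muscle genes (0.33, adjusted p = 0.0024; 3 of 23 higher, 5 higher and 1 lower adjusted over the list alone) were shifted up as well, and so were mechanical response genes (0.21, adjusted p = 0.0057; 2 of 22 higher, 2 adjusted over the list alone). In the order given, these last 3 had adjusted p = 0.054, 0.8 and 0.45 with an estimated correlation. The sum of smooth muscle genes hardly moved, at 7780 ± 525 CPM against 7470 ± 1330 CPM in midgut. No other list passed: anterior and middle HOX genes (-0.39, adjusted p = 0.088), epithelium (-0.09, 0.1), collagens (-0.15, 0.11) and mesothelium (-0.31, 0.11) came nearest. Matrix glycoproteins moved both ways (median -0.13, adjusted p = 0.28), with 3 higher and 5 lower adjusted over the list alone. Signs of median and test differed for Hedgehog response (median 0.06, mean -0.03, adjusted p = 0.76) and immediate early genes (0.05, -0.01, 0.91), and signs of median and mean for fibroblast genes (-0.01, 0.02, 0.87).

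Hindgut was compared with Hoxd13 midgut to see how far the misexpressing midgut remained from the hindgut. MYL12B was higher in hindgut by 2.24 ± 0.23 (log2, SE; adjusted p = 3.1e-06, 4 of 4 samples above all Hoxd13 midgut samples), and HBA1 by 1.96 ± 0.22 (adjusted p = 4.8e-06, 4 of 4). PTN was higher by 1.93 ± 0.33 (adjusted p = 0.0024, 3 of 4) and the antioxidant enzyme GPX3 by 1.41 ± 0.24 (adjusted p = 0.0024, 4 of 4). The adipokine ADIPOQ was higher by 2.86 ± 0.51 (adjusted p = 0.0032, 4 of 4) and HES1 by 1.90 ± 0.34 (adjusted p = 0.0032, 4 of 4). POSTN (1.11), THSD4 (1.27), PCOLCE (1.20), PRELP (0.78), COL6A3 (0.67), COL6A2 (0.63), COL1A1 (0.63) and COL6A1 (0.62) were higher. So were the muscle genes CSRP1 (1.04), DES (0.96), ACTG2 (0.89) and TPM2 (0.77, Z-linked) and the NOTCH pathway genes DLL1 (1.60) and NOTCH1 (0.66). GJA5 was lower in hindgut by -2.77 ± 0.33 (adjusted p = 1.8e-05, 4 of 4) and the membrane linker EZR by -1.17 ± 0.23 (adjusted p = 0.0075, 4 of 4). The defensin AvBD10 was lower by -2.05 ± 0.41 (adjusted p = 0.0096, 4 of 4) and ND4L by -0.65 ± 0.13 (adjusted p = 0.0096). AvBD10 was at 69.6 CPM in hindgut replicate 1 and 2.21 to 11.1 CPM in the other hindgut samples, so its fold leans on that sample. The epithelial genes CDH1 (-0.80), EPCAM (-0.72) and KRT7 (-0.70) and the mitotic genes BUB1 (-1.34), PLK1 (-0.66) and TOP2A (-0.47) were lower.

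In this comparison 158 genes passed the same test, 94 higher and 64 lower in hindgut, and 735 had an unadjusted p under 0.05. The count was 629 without hindgut replicate 1, 58, 71 and 67 without hindgut replicates 2 to 4 and 80, 58, 61 and 60 without Hoxd13 midgut replicates 1 to 4. With only these groups in the fit 71 genes passed. Of 52 named calls, 21 passed whichever sample was left out, among them MYL12B, HBA1, PTN, GPX3, ADIPOQ, HES1, POSTN, GJA5, EZR and AvBD10. COL1A1 did not pass without Hoxd13 midgut replicate 4 (adjusted p = 0.18), nor EPCAM without hindgut replicate 4 (adjusted p = 0.11).

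Collagens were shifted up in hindgut against the Hoxd13 midgut (median 0.50, camera adjusted p = 4.7e-07; 4 of 11 higher, 10 adjusted over the list alone), with matrix glycoproteins (0.51, adjusted p = 6.7e-07; 5 of 22, 8 adjusted over the list alone) and smooth muscle (0.50, adjusted p = 1.1e-05; 5 of 23, 8 adjusted over the list alone). In this order, adjusted p = 0.17, 0.17 and 0.31 with an estimated correlation. Shifted up too were crosslinking (0.24, adjusted p = 0.0042), endothelium (0.62, adjusted p = 0.0042), NOTCH signalling (0.07, adjusted p = 0.0052), basement membrane (0.30, adjusted p = 0.006) and fibroblast genes (0.24, adjusted p = 0.043). In this order, adjusted p = 0.11, 0.18, 0.11, 0.18 and 0.17 with an estimated correlation. Mitochondrial genes were shifted down (-0.46, adjusted p = 4.7e-07; 2 of 13 lower, 8 lower and 1 higher adjusted over the list alone; adjusted p = 0.18 with an estimated correlation). So were epithelium (-0.40, adjusted p = 4.9e-05; 3 of 22 lower, 9 lower and 2 higher adjusted over the list alone) and proliferation (-0.20, adjusted p = 0.0042; 3 of 27 lower, 5 adjusted over the list alone). These had adjusted p = 0.31 and 0.11 with an estimated correlation, so that none of the 11 lists passed with it. Without hindgut replicate 1 proliferation did not pass (adjusted p = 0.072). For enteric neurons and glia the median (-0.02) and mean (0.01) differed in sign (adjusted p = 0.92), as for interstitial cells of Cajal (-0.01 and 0.05, adjusted p = 0.92).

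**Figure D2:**
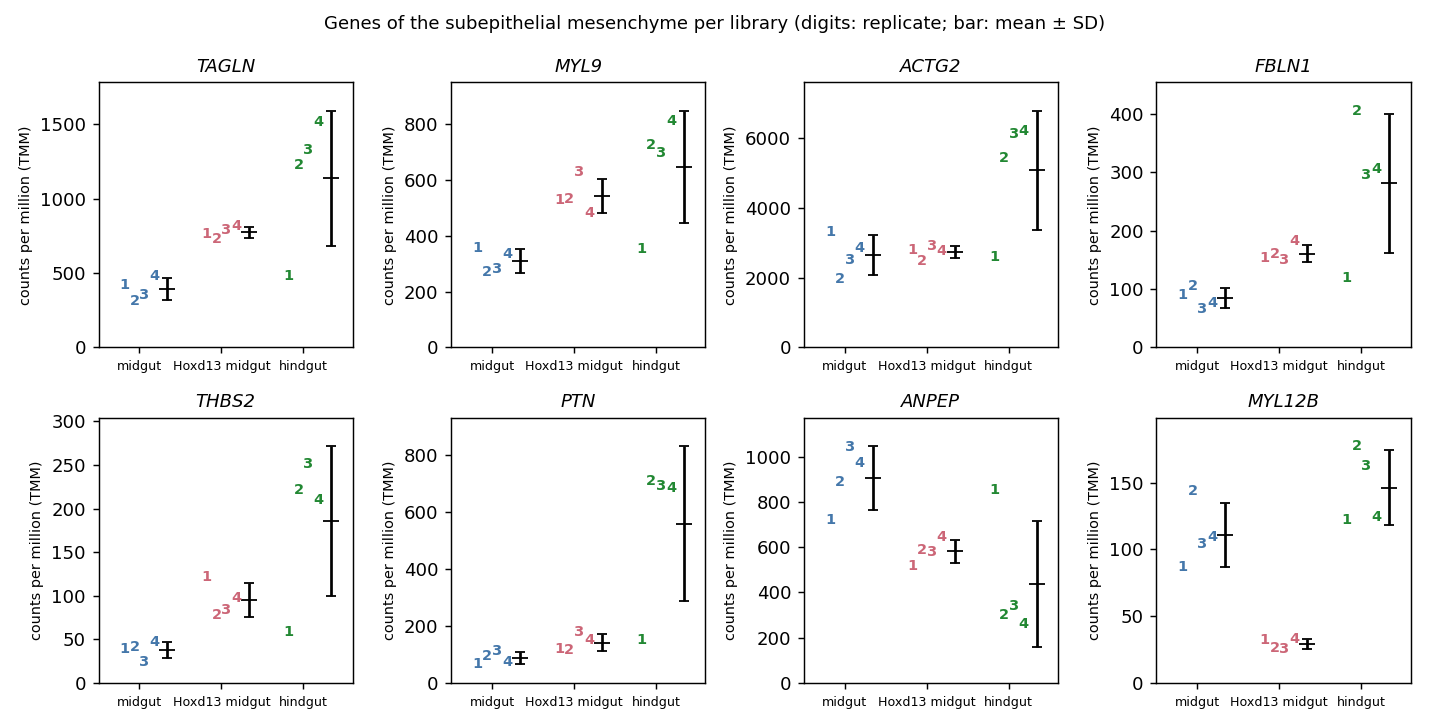
CPM (TMM library sizes) of TAGLN, MYL9, ACTG2, FBLN1, THBS2, PTN, ANPEP and MYL12B in each mesenchyme sample of the 3 groups; digits give the replicate and bars the mean ± SD. TAGLN averages 391, 773 and 1136 CPM in midgut, Hoxd13 midgut and hindgut, while MYL12B averages 111, 29.0 and 146 CPM.

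The series asked which genes change in common in the hindgut and in the Hoxd13 midgut. TAGLN (1.51 in hindgut, 0.98 with Hoxd13), MYL9 (1.02 and 0.79) and FHL3, a co-factor of muscle genes (0.87 and 0.71), were higher in both. So were TUT4, an RNA uridylyltransferase that was not matched to a chromosome (1.22 in each), HOXD13 and the W-linked HNRNPKL, HINTW and SPIN1W. RPS3A (-0.50 and -0.47) and the Z-linked RPL17 (-0.89 and -1.51) and NREP (-0.79 and -1.34) were lower in both. In all, 14 genes were higher and 3 lower in both comparisons, among them 6 with only an Ensembl identifier, and none moved in opposite directions. Independent lists of the same sizes would share 0.724 and 0.0939 genes. Unchanged groups simulated against the same midgut samples shared at most 1 in 50 simulations. As no gene was changed in them, they do not show how many genes the shared midgut samples add to lists of these sizes. Across genes, which are not independent replicates, the covariance of both log2 changes was 0.151 against 0.0426 in the simulations, an excess of 0.108, and their correlation was 0.609 against 0.507. When each comparison had its own pair of midgut samples, 0 to 2 genes were shared in the 6 assignments, and the covariance was 0.109 to 0.126.

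Of the 14 genes higher in both, 3 were W-linked and 4 lay on other chromosomes. These 4 were TAGLN, MYL9, FHL3 and HOXD13. HOXD13 was raised in the Hoxd13 midgut by design, so it is no shared response, although the counts of shared genes include it. The other 7 could not be matched to a chromosome, so that their sex linkage is unknown. Of the 3 lower in both, 2 were Z-linked. A fit without the matched Z- and W-linked genes, which kept the unmatched ones, shared 11 genes. Without hindgut replicate 1, 162 genes were shared, 69 higher and 93 lower, where independent lists would share 13.6 and 17.3, and 11 genes moved in opposite directions. THBS2, FBLN1, SMOC1, VCAN, ACTA2, ACTN1, TPM1, CALD1, MYL6, PTN, LRIG1 and TFRC were then higher in both, and ACE, PODXL, TBX3, ALDH1A3, ANPEP, ELN, CDX1, LAMA5 and MEP1A lower in both, beside 18 Z-linked genes that were lower. The genes named here are only a part of the 162 and were not all taken by the rule for named genes. With separate midgut pairs 83 to 100 genes were still shared, and the covariance excess over the simulations was 0.191. Of the 69 higher and 93 lower genes, 26 and 15 could not be matched to a chromosome. Hindgut replicate 1 was the only hindgut sample whose sum of Z-linked genes was not below midgut. Leaving it out thus made the sex-linked difference from midgut alike in both comparisons. Without the matched Z- and W-linked genes as well, 139 genes were shared, but sex was not separated from the shared change. The 17 genes became 6, 7, 7 and 5 without midgut replicates 1 to 4, 10 and 11 without Hoxd13 midgut replicates 2 and 3, and 8, 6 and 11 without hindgut replicates 2 to 4. When each comparison was fitted with only its own groups, 1 gene was shared.

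**Figure D3:**
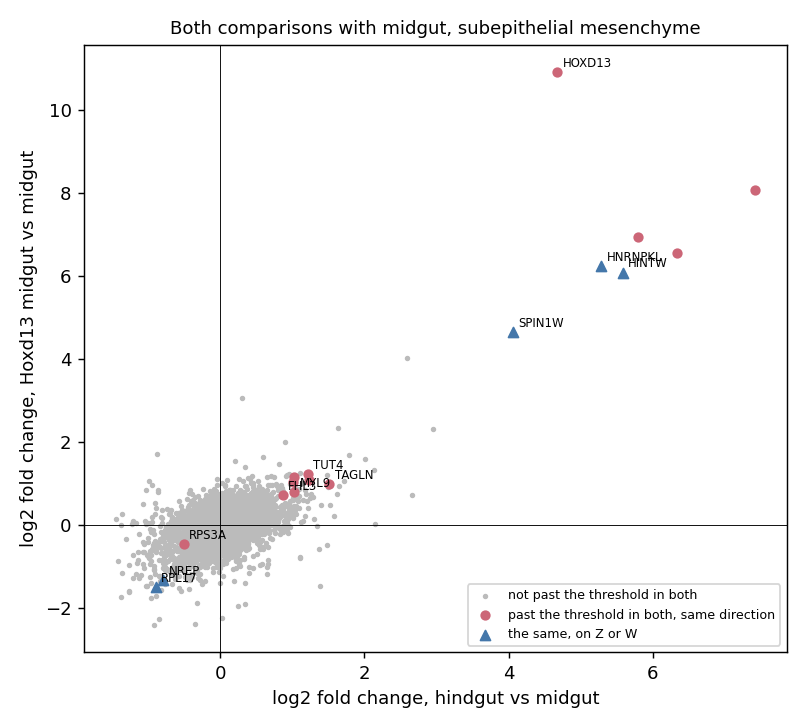
Fitted log2 change in hindgut against midgut (x axis) and in Hoxd13 midgut against midgut (y axis) for each gene tested in the mesenchyme; red circles passed in both comparisons in the same direction, and blue triangles are such genes on the Z or W chromosome. TAGLN lies at 1.51 and 0.98, and RPL17 at -0.89 and -1.51.

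The layers were compared to see whether the barcoded regions held the tissue their names give. Circumferential muscle was rich in contractile genes: TAGLN was higher than in mesenchyme by 1.20 ± 0.09 (log2, SE; adjusted p = 1e-19, in 11 of 12 samples). MYH11, the heavy chain of smooth muscle myosin, was higher by 1.21 ± 0.09 (adjusted p = 2e-19, 11 of 12), and DES by 1.33 ± 0.10 (adjusted p = 2.8e-19, 12 of 12), with MYL9 by 1.21, MYLK by 1.10 and ACTG2 by 1.07. The epithelial genes KRT7 (-0.98 ± 0.12, adjusted p = 2.8e-11, 12 of 12), KLF5 (-1.07), DSP (-1.03) and CDH1 (-0.93) and MYH9 (-0.82) were lower there. Longitudinal muscle was higher in ACTA2, smooth muscle actin (1.37 ± 0.14, adjusted p = 8.5e-13, 12 of 12), YTHDF2 (1.47), the matrix protein ASPN (1.40), TUBA1A (1.09), CORO1C (0.82) and MTSS2 (0.81). It was lower in the lipoprotein gene APOA1 (-2.11 ± 0.35, adjusted p = 1.1e-06, 12 of 12), FOXP4 (-1.48), CDH1 (-0.98), RPL5 (-0.89) and KRT7 (-0.78). RPSAP58 was lower in both muscle layers (-0.63 and -0.62).

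Of 614 genes tested by edgeR's quasi-likelihood test in a fit of all 36 columns, 246 differed between circumferential muscle and mesenchyme (129 higher, 117 lower) and 128 between longitudinal muscle and mesenchyme (61 higher, 67 lower). The latter count was 73 without hindgut replicate 1, where APOA1 no longer passed (adjusted p = 0.16). All 17 smooth muscle genes tested were higher in circumferential muscle, over all genes and adjusted over the list alone (median 1.07, camera adjusted p = 4.2e-19; adjusted p = 0.013 with an estimated correlation). All 6 epithelial genes tested were lower in both muscle layers, also adjusted over the list alone (medians -0.93 and -0.88, adjusted p = 0.00011 and 0.00025; adjusted p = 0.068 and 0.17 with an estimated correlation). Mitochondrial genes were shifted up in circumferential muscle (0.18, adjusted p = 0.0054; 10 of 13 higher, 10 adjusted over the list alone). They were in longitudinal muscle too (0.11, adjusted p = 0.037; 4 higher, 6 adjusted over the list alone), with adjusted p = 0.71 and 0.72 with an estimated correlation. In longitudinal muscle smooth muscle genes (0.30, adjusted p = 0.016; 5 of 17, 7 adjusted over the list alone) and glycoproteins (0.24, adjusted p = 0.037; 4 of 15, 5 adjusted over the list alone) passed, with adjusted p = 0.58 and 0.19 with an estimated correlation. Without hindgut replicate 1 these last lists and the mitochondrial list did not pass in longitudinal muscle (adjusted p = 0.13, 0.11 and 0.13). The average over groups hides a difference. Summed smooth muscle genes in longitudinal muscle and mesenchyme were at 11737 and 7470 CPM in midgut and at 8749 and 7780 CPM in Hoxd13 midgut. In hindgut they were at 11325 ± 2339 and 12755 ± 3065 CPM (SD, n = 4). Only hindgut replicate 1 had the larger sum in longitudinal muscle (14071 and 9382 CPM). By this sum the hindgut longitudinal region was not richer in contractile genes. Among lists that did not pass, signs of median, mean and test differed for collagens and mechanical response in longitudinal and for Hedgehog response in circumferential muscle.

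Within the muscle layers, the same comparisons asked whether hindgut and Hoxd13 also differed from midgut there. TUT4, whose sex linkage is unknown here, rose with Hoxd13 in longitudinal muscle (1.62 ± 0.25, adjusted p = 1.5e-05, 4 of 4 samples) and in circumferential muscle (1.54 ± 0.28, adjusted p = 0.0027, 4 of 4). The Z-linked tropomyosin TPM2 fell in both, by 1.19 (adjusted p = 0.026, 4 of 4) and 1.07 (adjusted p = 0.0045, 4 of 4). Longitudinal muscle with Hoxd13 gained the mitochondrial transcripts ND1 (0.76, adjusted p = 0.0027), ND4 (0.64, adjusted p = 0.0087), MT-ND2 (0.65, adjusted p = 0.0087) and CYTB (0.60, adjusted p = 0.016) and lost COL1A1 (-0.78, adjusted p = 0.016, 4 of 4). Without Hoxd13 midgut replicate 1 the mitochondrial transcripts did not pass (adjusted p = 0.21, 0.39, 0.34 and 0.5). Circumferential muscle with Hoxd13 lost SVEP1 (-2.11), the receptor LRP1 (-0.74), RPS10 (-0.82) and the Z-linked RPL17 (-1.65) and RPS6 (-1.60), each at adjusted p = 0.03 and in 4 of 4 samples. In hindgut longitudinal muscle TUT4 (1.11 ± 0.25, adjusted p = 0.015, 4 of 4) and TUBB (0.91 ± 0.24, adjusted p = 0.048, 4 of 4) rose, and neither passed without midgut replicate 1 (adjusted p = 0.18 and 0.31). MCAM (1.06, adjusted p = 0.067), COL5A1 (0.73, adjusted p = 0.093), TPM3 (1.09) and GAPDH (1.02, adjusted p = 0.12 each) followed.

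With Hoxd13, 17 of 144 genes passed in longitudinal muscle (15 higher, 2 lower) and 17 of 349 in circumferential muscle (9 higher, 8 lower). Without hindgut replicate 1 the longitudinal count was 12 higher and 13 lower, 25 of 129 genes tested. With DESeq2 size factors the longitudinal count was 8 higher and 4 lower and with TMMwsp factors 10 higher and 4 lower. There the median log2 change of all genes was 0.11 with TMM, 0.00091 with DESeq2 size factors and 0.04 with TMMwsp, and for hindgut 0.04, -0.06 and -0.10. The longitudinal count was 11, 10, 8 and 6 without midgut replicates 1 to 4 and 9 without Hoxd13 midgut replicate 1 or 3. The circumferential count was 6, 8, 8 and 6 without midgut replicates 1 to 4 and 7, 5, 5 and 9 without Hoxd13 midgut replicates 1 to 4. It was 29 without hindgut replicate 1 and 10 without hindgut replicate 4. For hindgut 2 genes passed in longitudinal muscle (15 at an unadjusted p under 0.05). This count was 0 without midgut replicate 1 or 4, any Hoxd13 midgut replicate or hindgut replicate 2 or 3, 4 without hindgut replicate 4 and 12 without hindgut replicate 1. In circumferential muscle 0 genes passed for hindgut with edgeR (37 at an unadjusted p under 0.05), 2 with DESeq2, 7 with limma voom and 7 with the replicate number as a block. The smallest p there belonged to MTSS2 (1.28) and MCAM (1.05, adjusted p = 0.078 each, 4 of 4 samples), FN1 (-0.80, adjusted p = 0.16), TUT4 (0.94), TUBB (0.64) and PTN (1.22, adjusted p = 0.2 each). That count was 1 without midgut replicate 3, 39 without hindgut replicate 1 and 3 without hindgut replicate 4. Mitochondrial genes were shifted up with Hoxd13 in longitudinal muscle (median 0.53, camera adjusted p = 9e-05; 7 of 13 higher, 10 adjusted over the list alone; adjusted p = 0.34 with an estimated correlation). So they were in circumferential muscle (0.42, adjusted p = 0.00081; 0 higher, 0 adjusted over the list alone; adjusted p = 0.45 with an estimated correlation). None of the 5 and 9 lists tested passed for hindgut (smallest adjusted p = 0.11 and 0.79). Signs of median, mean and test differed there for basement membrane and smooth muscle in longitudinal muscle (adjusted p = 0.82 and 0.83) and for smooth muscle in circumferential muscle (0.79).

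The difference between layers was tested to ask whether an effect was larger in the mesenchyme than in the muscle. For 3 smooth muscle genes the log2 change in hindgut was higher in mesenchyme than in muscle: ACTG2, enteric actin, by 1.09 ± 0.19 (log2, SE; adjusted p = 7e-05), TAGLN by 0.86 ± 0.22 and MYH11 by 0.85 ± 0.22 (adjusted p = 0.045 each). In longitudinal and circumferential muscle of hindgut ACTG2 was at -0.32 and -0.28, MYH11 at -0.16 and -0.35 and TAGLN at 0.49 and 0.37, none past the threshold. CSRP1 (1.14), TNS1 (0.58, adjusted p = 0.31 each) and COL1A1 (0.36, adjusted p = 0.82) came next. As a list, 17 smooth muscle genes had a median difference of 0.53 (camera adjusted p = 2.8e-17; 3 higher, 5 adjusted over the list alone; adjusted p = 0.01 with an estimated correlation). Collagens (0.21, adjusted p = 0.019) and mitochondrial genes (-0.11, adjusted p = 0.0001) also passed, with 0 genes past the threshold adjusted over the list alone and adjusted p = 0.64 and 0.69 with an estimated correlation. ACTG2 passed whichever sample was left out, but MYH11 did not without hindgut replicate 4 (adjusted p = 0.74) nor TAGLN without midgut replicate 4 (adjusted p = 0.87). The 3 calls became 1 without midgut replicate 1, 3 or 4, Hoxd13 midgut replicate 1 or hindgut replicate 2, 3 or 4.

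For Hoxd13, 0 genes passed in the test of the difference between layers with edgeR (49 at an unadjusted p under 0.05), 0 with DESeq2 and 2 with limma voom. COL4A2 (1.55), TUT4 (-0.45, adjusted p = 0.28 each), COL12A1 (higher, adjusted p = 0.36), PDGFA (-1.07), GLUL (-0.97) and ACTG2 (0.54, adjusted p = 0.44 each) had the smallest p. Without midgut replicate 1 the count was 2 and without midgut replicate 3 it was 1. Smooth muscle genes as a list were shifted towards the mesenchyme (median 0.43, camera adjusted p = 3.1e-05) and mitochondrial genes towards muscle (-0.22, adjusted p = 1.2e-08), with 0 genes of either past the threshold adjusted over the list alone. Both had adjusted p = 0.39 with an estimated correlation. Summed smooth muscle genes were at 7470 ± 1330 CPM in midgut and 7780 ± 525 CPM with Hoxd13 in the mesenchyme (SD, n = 4). They were at 11737 ± 1096 and 8749 ± 1427 CPM in longitudinal muscle, and at 20386.5 ± 5950 and 14434 ± 3668 CPM in circumferential muscle. By these sums the layers differed through lower values in muscle, while the mesenchyme was nearly level. Among lists that did not pass a test of the difference between layers, signs of median, mean and test differed for basement membrane, crosslinking, epithelium and immediate early genes in hindgut and for glycoproteins, Hedgehog response and mechanical response with Hoxd13.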

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

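Of the tests below, only that of muscle tissue inside the mesenchyme region was set before its result was seen; all the others were chosen after. Each group of 4 samples was searched for a sample apart from the other 3, in 216 groups of values, and chance sets a sample apart in about 1 in 20 of them. A sample stood apart in 22 groups: 6 of 76 groups of sample measures and 16 of 140 groups of single named genes. Hindgut replicate 1 was that sample in 15 of the 22.

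In the mesenchyme, hindgut replicate 1 lay at the midgut's side of the other hindgut samples for many genes. In CPM it had 6287 of summed epithelial genes (others 1820 to 2328), 853 of ANPEP (261 to 339), 69.6 of the defensin AvBD10 (2.21 to 11.1), 639 of PODXL (299 to 330), 455 of COTL1 (182 to 200) and 1280 of MYH9 (676 to 752). It had 2564 of RPS3A (1841 to 1923), 468 of NREP (200 to 237) and 527 of RPS6 (226 to 272). It had less PTN at 152 (684 to 710), CSRP1 at 138 (388 to 423) and HBAD at 94.3 (200 to 216). In its muscle layers, Z-linked genes summed to 17563 CPM in longitudinal muscle (others 10574 to 11306) and 18191 in circumferential muscle (10172 to 10629), and epithelial genes to 3210 in longitudinal muscle (1153 to 1424).

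Further samples apart were Hoxd13 midgut replicate 1 in longitudinal muscle, with 7060 CPM of Z-linked genes (others 8853 to 9051), and hindgut replicate 3 in longitudinal muscle, with 178 CPM of HOXD13 from 2 counts (others 0). NOV was at 174 CPM in Hoxd13 midgut replicate 3 (146 to 147) and SULT1C3 at 38.2 in midgut replicate 3 (19.1 to 21.6). Of the W-linked genes, HINTW stood at 2.40 and SPIN1W at 4.81 CPM in midgut replicate 1 and HNRNPKL at 3.42 in midgut replicate 2, with 0 in the other midgut samples. These were 1, 2 and 1 counts, and where the other 3 samples are at 0 any count sets a sample apart, so these 3 groups and that of HOXD13 say nothing. The hindgut effect differed between mesenchyme and muscle, in a test of that difference, for ACTG2 (1.09), MYH11 (0.85) and TAGLN (0.86).

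Embryos of different sex may account for the W- and Z-linked genes that set midgut apart from the other groups: with male midgut and female Hoxd13 midgut samples Z-linked genes would lie lower in the latter as a set. Their median was below that of other chromosomes by -0.40 (-0.52 to -0.31), with 75.4% of Z-linked and 48.5% of other genes below 0. If the 8 samples were separate embryos of random sex, the chance of single and opposite sexes in both groups would be 0.00781. The labels do not say whether samples share an embryo, so chance and shared embryos cannot be told apart. For genes off the sex chromosomes, effects of sex and of Hoxd13 or hindgut were not separated, as no midgut sample carried W-linked genes at the level of the other groups.

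Hindgut replicate 1 was not a sample of midgut alone under a hindgut label, because 7 posterior HOX genes that were at 0 in every midgut sample summed to 48 counts in it (HOXD12 at 0, the other 6 present). A mainly midgut sample with some hindgut RNA would hold such counts too, so that case stays open for hindgut replicate 1. Midgut RNA mixed into it would give the same hindgut share from each set of genes, and the share was 2.56% (-1.63 to 6.69) from genes lower in the other hindgut samples, 16.2% (8.05 to 24.4) from genes higher there, 18.5% (13.2 to 24.4) from posterior HOX genes, 20.6% (13.4 to 29.6) from W-linked genes, -4.13% (-19.3 to 5.13) from Z-linked genes and 8.49% (-10.3 to 24.4) from anterior HOX genes. The same estimate ran from 67.2% to 165% in hindgut replicates 2 to 4, a bound set after the values were seen, so mixing and other causes cannot be told apart, except for the mitochondrial share, which at 27.5% lay under the lowest other hindgut or midgut sample (33.0%; SD within groups 1.33). Depth may bear on part of the fewer calls but not on all of them, since with the sample thinned to the lowest hindgut total 314 to 368 genes were called in 10 thinnings, against 62 unthinned and 825 without it. No biological explanation was tested for this sample.

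For the higher smooth muscle genes in hindgut mesenchyme, a lower share of epithelial RNA would raise the markers of every other tissue alike. Smooth muscle genes instead exceeded enteric neuron and glia genes by a median of 0.79 (0.29 to 1.21, an interval over genes, not samples). Enteric genes summed to 1348 CPM in midgut and 1290 CPM in hindgut, but endothelial genes to 388 and 587 CPM. Measured against the enteric list, this argues against a lower epithelial share as the whole cause. No other list was set against smooth muscle in this way. Muscle tissue inside the hand-drawn mesenchyme region would raise other genes of the circumferential layer along with contractile ones. Against their enrichment in that layer, 16 smooth muscle genes had a slope of 0.84 and 78 other genes one of 0.40, and the latter minus 0.5 times the former was -0.0201 (-0.16 to 0.18), so carry-over and a change in the mesenchyme cannot be told apart. A larger contractile program of hindgut mesenchyme, the biological difference the design names, stays open and untested.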

How the results depend on the processing

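Alternatives without Z- and W-linked genes, without mitochondrial genes, with the former and hindgut replicate 1 left out together, and gene lists without hindgut replicate 1 were chosen after seeing the data. No named call reversed its direction with DESeq2 size factors, with DESeq2 or with the replicate block changed, and reversals of named genes were not counted under every setting. Where a count moved by more than 1.5 times, the cause was not tested, except that fits without a filter test more genes and fits without a sample test fewer samples. In hindgut against midgut the 62 genes became 231 without a filter, 112 with DESeq2, 520 with limma voom, 143 with the replicate block, 2 with only the compared groups in the fit, 754 with sex-linked genes and hindgut replicate 1 left out, 140 at a threshold of 0.1, and 14 to 825 when each sample was left out. The 111 for Hoxd13 became 172 without a filter, 66 with DESeq2, 270 with voom, 365 with only the compared groups, 284 without sex-linked genes and hindgut replicate 1, 184 at 0.1, and 37 to 317 by leaving out samples; the replicate block gave 79. The 158 for hindgut against Hoxd13 midgut became 427 with voom, 71 with only the compared groups, 613 without sex-linked genes and hindgut replicate 1, 270 at 0.1, and 58 to 629 by leaving out samples; the replicate block gave 146. The 17 shared genes became 67 without a filter, 119 with voom, 26 with the replicate block, 1 with only the compared groups, 11 without sex-linked genes, 139 without these and hindgut replicate 1, 38 at 0.1, and 5 to 162 by leaving out samples.

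Between layers, the 128 for longitudinal muscle became 2630 without a filter, 78 with the stricter filter, 67 with no replicate block for the samples, 73 without sex-linked genes and hindgut replicate 1, and 73 to 129 by leaving out samples. The 246 for circumferential muscle became 1654 without a filter and 128 with the stricter one, and 193 to 272 by leaving out samples. In longitudinal muscle the 2 hindgut genes became 1 with DESeq2 size factors, 0 with TMMwsp, without a filter, with the stricter filter and with only the compared groups, 1 with DESeq2 and without sex-linked genes, 5 with voom, 4 with the replicate block, 11 without sex-linked genes and hindgut replicate 1, 5 at 0.1, and 0 to 12 by leaving out samples. The 17 for Hoxd13 there became 11 without a filter, 26 with voom and with only the compared groups, 11 without mitochondrial genes, and 6 to 25 by leaving out samples. In circumferential muscle the 0 hindgut genes by edgeR became 7 without a filter, 5 with the stricter one, 2 with DESeq2, 7 with voom and with the replicate block, 34 without sex-linked genes and hindgut replicate 1, 2 at 0.1, and 0 to 39 by leaving out samples; 37 had an unadjusted p under 0.05. The 17 for Hoxd13 there became 28 without a filter, 33 with voom, 38 with only the compared groups, 10 without sex-linked genes, and 5 to 29 by leaving out samples. The difference between layers gave for hindgut 1 in place of 3 genes with DESeq2 size factors, without a filter and with DESeq2, 0 with voom and with no replicate block, and 1 to 4 by leaving out samples. For Hoxd13 it gave 2 in place of 0 with voom (49 at an unadjusted p under 0.05, 0 with DESeq2) and 0 to 2 by leaving out samples.

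Of 38 list calls, 2 held with an estimated correlation, fry called 40 lists (25 of them the same), and 38, 36 and 43 lists passed with DESeq2 size factors, with the replicate block changed and without hindgut replicate 1. Of 165 named calls, 157 held with DESeq2 size factors, 122 with DESeq2, 148 with the replicate block changed and 78 in every fit with a sample left out. Replicate numbers were not seen to pair the samples of the mesenchyme: deviations from group means correlated between -0.274 and 0.0946 for the same number in the mesenchyme, where a sample correlated best with its own number in 4 of 12 cases. These correlations ran from -0.245 to 0.228 in longitudinal (best in 5 of 12) and from -0.231 to 0.210 in circumferential muscle (best in 6 of 12), with 6 and 4 of 12 over 0.1. As the layers of a sample share 1 library, pairing by number stays open for the samples in all layers. W-linked genes summed to at most 7.0 CPM in midgut mesenchyme and to at least 157 CPM in Hoxd13 midgut and 43.2 CPM in hindgut. These sums argue against midgut samples sharing an embryo with samples of the other groups. Depth limits the muscle layers most, where 144 and 349 genes could be tested against 4176 in the mesenchyme.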

Other observations

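All tests in this part, regroupings of the samples included, were chosen after the results were seen. Some genes outside the rule for named genes were chosen after their values were seen, as they had few or no counts in midgut mesenchyme. The stomach and gut transcription factor BARX1 had 50 counts in hindgut, 6 in the Hoxd13 midgut and 3 in midgut, a ratio to midgut of 12.6 in hindgut (95% counting interval 4.07 to 63.2) and 1.88 (0.401 to 11.6) in the Hoxd13 midgut. The transcription factor FOXD2 had 27 counts in hindgut and 0 in midgut (6.81-fold above the midgut floor). CRHR2, a receptor for urocortins, had 33 against 1 (a ratio of 25.0, counting interval 4.18 to 1015). The identifier ENSGALG00000041221, without a name in the files, had 112 counts in the Hoxd13 midgut, 91 in hindgut and 0 in midgut (35.1-fold and 22.9-fold above the midgut floor). This is the pattern of the W-linked genes, and as the identifier could not be matched to a chromosome, its sex linkage is unknown.

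Other splits of the same samples were counted for each result. They exchange single samples, so they exclude neither a difference of sex between groups nor, if samples of a group share an embryo, one between embryos. A share of 1 of 35 is the smallest that 35 splits can give, and shares were not adjusted over the results tested. Taking the samples as independent, no other split reached the real count for Hoxd13 against midgut in the mesenchyme. There 1 of 35 splits, the real one, gave as many as 111 genes, and the highest other gave 0. The same held for Hoxd13 in longitudinal muscle (1 of 35; 17 genes, highest other 1), Hoxd13 in circumferential muscle (1 of 35; 17, highest other 2), and longitudinal muscle against mesenchyme (1 of 100; 128, highest other 68). It held for circumferential muscle against mesenchyme (1 of 100, with 246 genes and 38 in the highest other). For the shared genes 1 of 100 regroupings, the real one, gave as many as 17, and the highest other gave 0. These regroupings remove both group differences at once. They do not test whether genes are shared by chance or through the same midgut samples. Chance was not excluded for hindgut against midgut (5 of 35; 62, highest other 423), hindgut against Hoxd13 midgut (2 of 35; 158, highest other 165), or hindgut in longitudinal muscle (7 of 35; 2, highest other 6). Nor was it for the difference between layers for hindgut (6 of 35, with 3 genes and 14 in the highest other). Hindgut in circumferential muscle and the difference between layers for Hoxd13 had 0 genes (highest other 13 and 3). Every split gives at least 0 genes, so 35 of 35 was fixed in advance and the splits say nothing there. The split with 423 genes set hindgut replicate 1 and midgut replicates 2 to 4 against the other samples, which points to the structure given by hindgut replicate 1. That sample was left out only after its values were seen, so the splits without it do not settle whether chance is excluded for hindgut against midgut (1 of 35; 825, highest other 239) or against Hoxd13 midgut (1 of 35; 629, highest other 129).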
